A study of Homo sapiens with 12 samples.

How the data were processed

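Per the protocols, 100 ng of RNA of 12 samples labelled PC3 was biotin labelled by a 3-prime in vitro transcription kit and hybridised to Affymetrix arrays. The deposited values are intensity values, 1 per probe set and array, and the submitters' processing notes name Partek 6.5 and RMA. The order of steps, background correction and scanner software are not given. The values themselves are linear, from 0.0212 to 17908, with a 2% trimmed mean of 150 on every array and medians of 17.7 to 23.1 on the 11 arrays compared. They lack the log2 scale and equal distributions of RMA output, so they were log2 transformed here and not normalised again. No detection calls were used here.

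Per the labels, the submitters removed control replicate 2 for weak signal, and it was left out of the comparisons here. Nothing says that the replicates were separate cultures, so each p-value measures only the spread between these samples, which may be technical.

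Of 54675 probe sets, 62 were array controls, 41091 carried 1 gene symbol, 1801 several and 11721 none. For each symbol the probe set with the highest mean over the 11 arrays was kept, which left 19775 genes. 42 symbols were not found by gene ID in the annotation used. No pair of arrays held identical values.

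Genes were tested with limma 3.58.1 in R 4.3.3, with a mean per group over the 11 arrays, moderated t-tests on 7 residual degrees of freedom, a prior of 1.12 degrees of freedom and a prior SD of 0.192 (log2). P-values were adjusted by Benjamini and Hochberg over all genes, and a gene was called at an adjusted p under 0.05. The 6 comparisons were each treated group against control, both drugs against each single drug, and the interaction of the drugs on the log2 scale. Errors of log2 fold changes are the standard errors of this fit, and a signal is the geometric mean of a group. The call procedure was tested on simulated data with few planted changes, 72, 70 and 67 of them 2-fold. It called 34.7% of these for Wee1 inhibitor II, 21.4% for 17-AAG and 53.7% for both drugs against control. Among unchanged genes 3, 6 and 6 were called. With far more real calls the cutoff is looser, so these rates do not describe the real fits.

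Gene lists were tested with camera in limma, with its preset correlation between genes and adjustment over the lists within a comparison. Counts of members called are given from the test over all genes and from p-values adjusted over the list alone. The 31 lists were heat shock response, Hsp90 clients, pro-apoptotic genes of the mitochondrial pathway, anti-apoptotic genes, death receptor pathway, mitosis and G2/M, DNA replication and G1/S, G2 checkpoint kinases, phosphatases and partners, homologous recombination and Fanconi genes, p53 targets, CDK inhibitors with D cyclins and RB family genes, unfolded protein response, ATF4 targets, cholesterol synthesis and its regulation, NRF2 and oxidative stress, metallothioneins with SLC30A1, aryl hydrocarbon receptor targets, glucocorticoid receptor targets, hypoxia and glycolysis, inflammatory and NF-kB targets, interferon response, proteasome, cytosolic ribosomal proteins, polyadenylated histone genes, autophagy and lysosome, epithelial and mesenchymal genes, MAPK and immediate early genes, actin cytoskeleton with SRF or YAP targets, and markers of fibroblasts, blood cells and androgen-responsive prostate lines. Of 804 distinct symbols in them 721 were measured.

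The groups, comparisons, tests, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule named, among called genes whose arrays did not overlap between groups, the 8 largest rises and falls (4 for both drugs against Wee1 inhibitor II and for the interaction). It also named up to 4 members with the smallest p of each list that passed or had a called member, and 15 genes of the drug targets, cell cycle and apoptosis. Of these 15, HSPA1A and BBC3 were not among the genes tested. The text leaves out some of them for length. Chosen after seeing the data were the ranking among genes with a signal of at least 100, the setting of signals below 32 to 32, the marker genes of control replicate 2 and the pigment cell list.

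Alternatives were control replicate 2 included with and without array weights, array weights on the 11 arrays, the replicate number as a block, trended and robust empirical Bayes, quantile normalisation, centring each array on its median, leaving out the dimmest 40% of genes, every probe set on its own, the mean of a gene's probe sets, and a fit of only the arrays compared. Further alternatives were a change of at least 2-fold, an adjusted p under 0.01, the floor of 32, only bright genes, camera with an estimated correlation, fry, and each of the 11 arrays left out in turn. Overlaps between comparisons that share the control arrays were set beside 100 simulations of unchanged groups.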

Results

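RNA of 12 samples labelled PC3, a prostate cancer line, was measured on Affymetrix 3-prime expression arrays. The samples formed 4 groups of 3: untreated control, Wee1 inhibitor II at 2.5 µM, 17-AAG at 40 nM, and both drugs. Wee1 is the kinase that holds CDK1 inactive until mitosis, and 17-AAG blocks Hsp90, the chaperone that keeps many kinases and receptors folded. 17-AAG was added 24 h after Wee1 inhibitor II and RNA was taken 48 h after 17-AAG. By its title, the study asked whether Wee1 inhibition makes prostate cancer cells more sensitive to an Hsp90 inhibitor and engages the intrinsic apoptotic pathway. The submitters left out control replicate 2 for weak signal, so the comparisons rest on 11 arrays, 2 of control and 3 of each treated group.

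The 11 arrays resembled each other closely. Pearson's r of log2 signals across probe sets was 0.948 to 0.956 between replicates and at least 0.935 for any pair. The median SD within groups was 0.08 (log2) for genes with a mean signal over 1024 and 0.11 from 256 to 1024. It was 0.17 from 64 to 256, 0.37 from 16 to 64 and 1.02 below 16. The ACTB probe sets at the 3-prime and 5-prime ends differed by 0.69 ± 0.03 (log2, SD, n = 2) on the control arrays and 0.68 ± 0.10 (n = 3) on those with Wee1 inhibitor II, against 0.96 ± 0.08 (n = 3) with 17-AAG and 0.96 ± 0.05 (n = 3) with both drugs. The median log2 fold change of all 19775 genes lay at 0.12 for Wee1 inhibitor II, 0.02 for 17-AAG and 0.11 for both drugs against control, at 0.10 for both drugs against 17-AAG, at 0.00 against Wee1 inhibitor II and at -0.03 for the interaction. List medians are given relative to it. Among genes with a signal of at least 100 it was 0.01 for Wee1 inhibitor II, 0.05 for both drugs and 0.04 against 17-AAG. Falls of bright lists thus look larger there than as measured.

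Control replicate 2 carried a different set of transcripts from the 11 other arrays. It correlated with the 11 others at only 0.836 to 0.846, and 391 genes were at least 4-fold above, and 276 at least 4-fold below, every other array at a signal of 200 or more, where no other array had any such gene. The pigment cell genes MLANA and PMEL had signals of 2.67 and 2.90 there against 2870 to 9920 and 3690 to 9200 on the 11 others. CTNNA1 and STAT3, which PC3 lacks through homozygous deletion, had signals of 1.57 and 7.54 against 2560 to 5040 and 819 to 1300. The prostate transcription factor gene HOXB13 had a signal of 2090 against at most 11.3, and the epithelial adhesion gene EPCAM 1100 against at most 26.2. Of 13 epithelial markers 8 lay above all 11 arrays and 1, ESRP1, below (48.5 against 142 to 728). These markers were picked after their values were seen. Its hybridisation controls averaged 10.24 (log2) against 10.28 to 10.73 on the others.

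**Figure D1:**
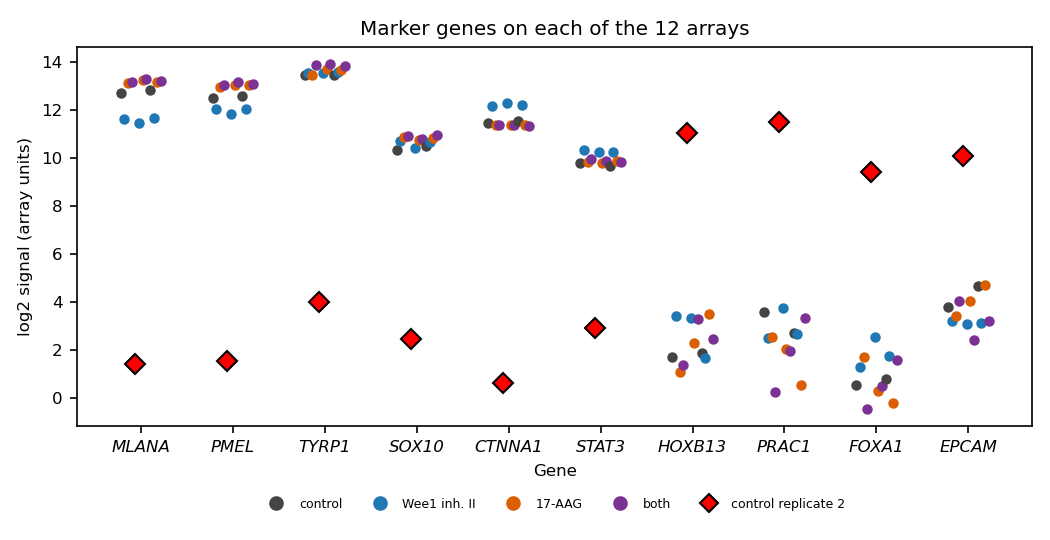
Log2 signal (array units) of 10 marker genes on the 12 arrays, 1 point per array, coloured by group, with control replicate 2 as a red diamond. MLANA has a signal of 2.67 on control replicate 2 and 2870 to 9920 on the other 11 arrays, and HOXB13 2090 against at most 11.3.

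On the arrays with Wee1 inhibitor II alone, most measured ATF4 target genes rose and most measured genes of DNA replication fell. Of 31 measured ATF4 target genes, transcripts induced when amino acids run short, 26 rose and 2 fell: asparagine synthetase ASNS rose from a signal of 1270 to 6500 and PHGDH, the entry enzyme of serine synthesis, from 641 to 2510. Of 52 measured genes of DNA replication and the G1/S transition 38 fell and 1 rose: CCNE2, which codes for cyclin E2, fell from 930 to 335, and the riser was CCND1, which codes for cyclin D1, from 994 to 1850. The acute phase gene SERPINA3 rose from 52.9 to 1330, a log2 fold change of 4.66 ± 0.21 (SE; adjusted p = 1.81e-05). This comparison shows what the inhibitor did without 17-AAG. In limma, 2877 genes rose and 2045 fell at an adjusted p under 0.05, 4922 of 19775, among them 3978 with a signal of at least 100 in either group.

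Of the 16 largest changes, 14 belonged to genes with a signal under 100 in both groups, such as ST7-AS1 (5.02 ± 1.02, adjusted p = 0.00834) and MGP (-4.70 ± 0.86, adjusted p = 0.00518). Both values are rough, and that of MGP became 0 with signals below 32 set to 32. Among brighter genes, the complement protease gene C1S rose by 4.38 ± 0.19 (adjusted p = 1.44e-05), NNMT by 4.26 ± 0.24 (adjusted p = 4.46e-05) and the transcription factor gene KLF4 by 3.80 ± 0.19 (adjusted p = 2.66e-05). The control signal of C1S (16.2) lies below the array medians of 17.7 to 23.1, so its fold change is only rough. ID3, an inhibitor of basic helix-loop-helix factors, changed by -2.71 ± 0.11 (adjusted p = 1.44e-05), PPARGC1A, a coactivator of mitochondrial biogenesis, by -2.53 ± 0.11 (adjusted p = 1.44e-05), and the iron transporter gene SLC11A2 by -2.26 ± 0.09 (adjusted p = 1.44e-05).

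The pigment cell list, drawn up after its values were seen, had 5 of 17 genes higher and 9 lower (median -0.30 as measured, camera p = 0.0209 without adjustment, and p = 0.218 with an estimated correlation). The ATF4 targets shifted by a median of 1.18 relative to all genes (camera adjusted p = 2.39e-11, and adjusted p = 0.242 with an estimated correlation; 26 rose and 2 fell adjusted over the list alone). ASNS changed by 2.36 ± 0.14 (adjusted p = 4.88e-05), PHGDH by 1.97 ± 0.10 (adjusted p = 3.09e-05) and WARS1, a tRNA synthetase gene, by 1.96 ± 0.14 (adjusted p = 7.99e-05). Of 22 MAPK and immediate early genes 14 rose and 1 fell (15 and 1 adjusted over the list alone). The MAPK list stood at a median of 0.66 (camera adjusted p = 4.71e-05, and adjusted p = 0.236 with an estimated correlation), with JUN at 2.30 ± 0.26 (adjusted p = 0.000532). Of 21 targets of SRF or YAP, genes of the actin cytoskeleton, 10 rose and none fell (11 and 0 adjusted over the list alone). The SRF or YAP list stood at a median of 0.27 (camera adjusted p = 0.00641, and adjusted p = 0.0997 with an estimated correlation), with CCN1 at 2.04 ± 0.13 (adjusted p = 5.97e-05). Of 14 histone genes with polyadenylated transcripts 10 rose and none fell (11 and 0 adjusted over the list alone). The histone list stood at a median of 0.95 (camera adjusted p = 2.85e-05, and adjusted p = 0.0997 with an estimated correlation), with H2BC12 at 2.38 ± 0.10 (adjusted p = 1.44e-05). Of 10 genes of the metallothionein list, which are 9 metallothioneins and the zinc transporter gene SLC30A1, 5 rose and none fell (5 and 1 adjusted over the list alone). The metallothionein list stood at a median of 1.01 (camera adjusted p = 0.0419, and adjusted p = 0.233 with an estimated correlation). MT2A changed by 1.22 ± 0.11 (adjusted p = 0.000222). The list's call was lost without control replicate 3 (0.92 as measured) and without 17-AAG replicate 2, combination replicate 1 or combination replicate 2 (1.13 each). It was also lost with a replicate block, with every probe set tested and with the mean of a gene's probe sets. Of 44 cytosolic ribosomal protein genes 33 rose and none fell (40 and 0 adjusted over the list alone). The ribosomal protein list stood at a median of 0.24 (camera adjusted p = 4.32e-11, and adjusted p = 0.361 with an estimated correlation), with RPL3 at 0.60 ± 0.08 (adjusted p = 0.00144).

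The replication genes had a median of -0.69 relative to all genes (camera adjusted p = 1.06e-18, and adjusted p = 0.0997 with an estimated correlation; 42 fell and 1 rose adjusted over the list alone), with RPA2 at -1.06 ± 0.08 (adjusted p = 0.000135). Of 27 genes of homologous recombination and the Fanconi pathway 13 fell and 1 rose (15 and 2 adjusted over the list alone). The recombination list stood at a median of -0.55 (camera adjusted p = 2.88e-07, and adjusted p = 0.0147 with an estimated correlation), with the exonuclease gene EXO1 at -1.20 ± 0.10 (adjusted p = 0.000164). Among 52 genes of mitosis and G2/M 17 fell and 2 rose (20 and 3 adjusted over the list alone). The mitosis list stood at a median of -0.31 (camera adjusted p = 6.45e-05, and adjusted p = 0.233 with an estimated correlation), with the kinetochore gene SPC25 at -1.38 ± 0.16 (adjusted p = 0.000695). Among 25 G2 checkpoint genes 7 fell and 2 rose (8 and 2 adjusted over the list alone). The G2 checkpoint list stood at a median of -0.25 (camera adjusted p = 0.0175, and adjusted p = 0.121 with an estimated correlation), with the phosphatase gene CDC25A at -1.90 ± 0.29 (adjusted p = 0.00236), and its call was lost without the dimmest 40% of genes. WEE1 itself stood at 0.27 ± 0.11 (adjusted p = 0.111).

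Of 28 heat shock genes 14 fell and 2 rose (14 and 2 adjusted over the list alone). The heat shock list stood at a median of -0.52 (camera adjusted p = 3.80e-06, and adjusted p = 0.233 with an estimated correlation): the co-chaperone gene DNAJB1 changed by -0.72 ± 0.09 (adjusted p = 0.00111), while SERPINH1, a collagen chaperone, changed by 1.87 ± 0.10 (adjusted p = 3.09e-05). HSP90AA1 (-0.09 ± 0.11, adjusted p = 0.607) and HSP90AB1 (-0.04 ± 0.09, adjusted p = 0.812) did not pass. Of 30 proteasome genes 15 fell and 1 rose (22 and 1 adjusted over the list alone). The proteasome list stood at a median of -0.46 (camera adjusted p = 1.59e-08, and adjusted p = 0.249 with an estimated correlation), with PSMD12 at -0.81 ± 0.11 (adjusted p = 0.00108). Of 33 genes of hypoxia and glycolysis 15 fell and 4 rose (17 and 6 adjusted over the list alone). The hypoxia list stood at a median of -0.46 (camera adjusted p = 0.000653, and adjusted p = 0.120 with an estimated correlation), with PFKFB4 at -1.26 ± 0.11 (adjusted p = 0.000217). Of 21 genes of cholesterol synthesis and its regulation 8 fell and none rose (8 and 0 adjusted over the list alone). The cholesterol list stood at a median of -0.31 (camera adjusted p = 0.000692, and adjusted p = 0.228 with an estimated correlation), with ACAT2 at -1.33 ± 0.14 (adjusted p = 0.000377). With each array centred on its median, 1444 genes rose and 2875 fell in this comparison, against 2877 and 2045 as deposited. The count was 3225 without control replicate 3, 1268 with control replicate 2 included, 2461 in a fit of these arrays alone and 3215 with the mean of a gene's probe sets, which also ended the calls of PPARGC1A (-1.79) and PFKFB4 (-1.08).

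With 17-AAG alone, 23 of 31 measured ATF4 target genes rose and none fell. Of 28 measured heat shock genes, of 34 listed, 14 fell and none rose. INSIG1, a sterol-regulated gene of the cholesterol pathway, rose from a signal of 306 to 1340. Of 21 measured cholesterol genes 9 rose and none fell. DNAJB1, which heat shock factor induces, fell from 1190 to 510. ID3 fell from 998 to 93.4 (log2 fold change -3.42 ± 0.11, adjusted p = 1.85e-05), with its relatives ID1 (-3.36 ± 0.22, adjusted p = 0.000226) and ID2 (-1.99 ± 0.13, adjusted p = 0.000226). As labelled, this comparison shows 17-AAG without Wee1 inhibitor II. An exchange of the control and 17-AAG labels was not excluded, and it would turn each sign here and change the reference of the other comparisons with either group. In limma 1964 genes rose and 1345 fell, 3309 in all, 2781 of them with a signal of at least 100 in either group.

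Of the 16 largest changes 15 belonged to genes with a signal under 100 in both groups, such as P2RY6 (3.65 ± 0.78, adjusted p = 0.0153) and TGFBI (-4.08 ± 0.48, adjusted p = 0.00156). Both calls were lost with signals below 32 set to 32 (0 and -0.335), so these values are rough. Among brighter genes, NOX4, an oxidase that makes hydrogen peroxide, changed by 3.27 ± 0.25 (adjusted p = 0.00037), the immediate early gene EGR1 by 3.04 ± 0.37 (adjusted p = 0.00187), the transcription factor gene ZEB1 by 3.02 ± 0.29 (adjusted p = 0.000713) and PDK4 by 2.57 ± 0.15 (adjusted p = 0.000226). Beside them, 11 of 17 pigment cell genes, a list drawn up after the values were seen, rose and none fell (median 0.41 as measured, camera p = 1.01e-07 without adjustment, and p = 0.0169 with an estimated correlation). ZEB1 in control (17.9) and DKK1 with 17-AAG (15.8) had signals near or below the array medians, so their fold changes are rough. The Wnt antagonist gene DKK1 changed by -2.71 ± 0.23 (adjusted p = 0.000503) and the collagenase gene MMP8 by -1.91 ± 0.15 (adjusted p = 0.000436).

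The heat shock list had a median of -0.38 relative to all genes (camera adjusted p = 5.98e-08, and adjusted p = 0.228 with an estimated correlation; 17 fell and 1 rose adjusted over the list alone). DNAJB1 changed by -1.23 ± 0.09 (adjusted p = 0.000375), DNAJA1 by -1.12 ± 0.13 (adjusted p = 0.00144) and CHORDC1, which codes for an Hsp90 partner, by -1.08 ± 0.09 (adjusted p = 0.000503). HSP90AB1 (-0.28 ± 0.09, adjusted p = 0.0678; called at -0.35 without 17-AAG replicate 2) and HSF1 (0.17 ± 0.19, adjusted p = 0.641) did not pass. HSPA1A was not among the genes tested. Of 29 Hsp90 clients 3 rose and 3 fell (3 and 3 adjusted over the list alone), and that list did not pass (camera adjusted p = 0.978). Among 30 proteasome genes 15 fell and none rose (18 and 1 adjusted over the list alone). The proteasome list stood at a median of -0.39 (camera adjusted p = 2.75e-09, and adjusted p = 0.316 with an estimated correlation), with PSMD12 at -1.03 ± 0.11 (adjusted p = 0.000888). The ACTB gap was wider on these arrays (0.96 against 0.69).

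The cholesterol genes had a median of 0.53 (camera adjusted p = 2.19e-07, and adjusted p = 0.111 with an estimated correlation; 13 rose and 0 fell adjusted over the list alone), with INSIG1 at 2.13 ± 0.18 (adjusted p = 0.000503) and the desaturase gene SCD at 1.00 ± 0.07 (adjusted p = 0.000286). The ATF4 list stood at a median of 0.89 (camera adjusted p = 4.96e-14, and adjusted p = 0.254 with an estimated correlation; 26 rose and 0 fell adjusted over the list alone), with ASNS at 1.71 ± 0.14 (adjusted p = 0.000436) and CHAC1 at 2.64 ± 0.29 (adjusted p = 0.00122). Among 22 MAPK genes 9 rose and 1, FOSL1 (-1.43 ± 0.19, adjusted p = 0.00255), fell (12 and 1 adjusted over the list alone). The MAPK list stood at a median of 0.50 (camera adjusted p = 0.000343, and adjusted p = 0.347 with an estimated correlation). Of 52 replication genes 28 fell and none rose (38 and 0 adjusted over the list alone). The replication list stood at a median of -0.49 (camera adjusted p = 1.39e-16, and adjusted p = 0.111 with an estimated correlation), with the ribonucleotide reductase gene RRM2 at -1.14 ± 0.11 (adjusted p = 0.000741). Among the 52 mitosis genes 16 fell and none rose (24 and 1 adjusted over the list alone). The mitosis list stood at a median of -0.31 (camera adjusted p = 3.95e-09, and adjusted p = 0.115 with an estimated correlation). Of 25 G2 checkpoint genes 8 fell and 3 rose (11 and 4 adjusted over the list alone). The G2 checkpoint list stood at a median of -0.30 (camera adjusted p = 0.00713, and adjusted p = 0.111 with an estimated correlation), with CCNB1, which codes for cyclin B1, at -0.49 ± 0.08 (adjusted p = 0.00598), and its call was lost with every probe set tested. Of 27 recombination genes 10 fell and none rose (13 and 0 adjusted over the list alone). The recombination list stood at a median of -0.34 (camera adjusted p = 2.53e-06, and adjusted p = 0.0249 with an estimated correlation), with RAD51C at -1.04 ± 0.13 (adjusted p = 0.00202). A fit of these 5 arrays alone called 0 genes in limma, with 4816 at an unadjusted p under 0.05, and the fit with control replicate 2 included called 480. The count was 1728 without control replicate 1, 1705 without control replicate 3, 2158 without 17-AAG replicate 1, 2204 with each array centred on its median and 1768 with the mean of a gene's probe sets. That mean also ended the calls of ASNS (1.52), CHORDC1 (-1.11) and PDK4 (1.77).

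With both drugs, genes of the cell division cycle fell together. All 52 measured genes of mitosis and G2/M fell against control, and 51 of 52 replication genes fell and 1 rose. RRM2 fell from a signal of 4670 to 330 (log2 fold change -3.82 ± 0.11, adjusted p = 5.54e-06), E2F8, a repressor in the E2F family, from 532 to 44.5 (-3.58 ± 0.11, adjusted p = 5.54e-06), the proliferation marker MKI67 from 477 to 49.3 (-3.27 ± 0.31, adjusted p = 0.000161) and CDK1 from 3720 to 962 (-1.95 ± 0.18, adjusted p = 0.000154). WEE1 fell from 789 to 378 (-1.06 ± 0.11, adjusted p = 0.000213). As labelled, the comparison shows the whole effect of both drugs in these cells. In limma 3306 genes rose and 2233 fell, 5539 in all, 4472 of them with a signal of at least 100 in either group.

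The mitosis list had a median of -1.88 relative to all genes (camera adjusted p = 4.83e-48, and adjusted p = 0.0019 with an estimated correlation; 52 fell adjusted over the list alone). The kinesin gene KIF4A changed by -2.20 ± 0.08 (adjusted p = 5.73e-06) and the separase gene ESPL1 by -2.26 ± 0.08 (adjusted p = 5.73e-06). The replication list had a median of -1.74 (camera adjusted p = 2.33e-39, and adjusted p = 0.0123 with an estimated correlation; 51 fell and 1 rose adjusted over the list alone), with the primase gene PRIM1 at -2.05 ± 0.08 (adjusted p = 6.77e-06). Of 25 G2 checkpoint genes 18 fell and 1 rose (18 and 3 adjusted over the list alone). The G2 checkpoint list stood at a median of -1.05 (camera adjusted p = 1.85e-10, and adjusted p = 0.0019 with an estimated correlation), with CCNB1 at -1.47 ± 0.08 (adjusted p = 1.98e-05) and PKMYT1, the other kinase that restrains CDK1, at -1.73 ± 0.12 (adjusted p = 4.38e-05). Of 27 recombination genes 20 fell and 1 rose (22 and 1 adjusted over the list alone). The recombination list stood at a median of -0.93 (camera adjusted p = 1.01e-14, and adjusted p = 0.0013 with an estimated correlation), with EXO1 at -2.96 ± 0.10 (adjusted p = 5.73e-06) and FANCI at -1.93 ± 0.09 (adjusted p = 1.24e-05).

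**Figure D2:**
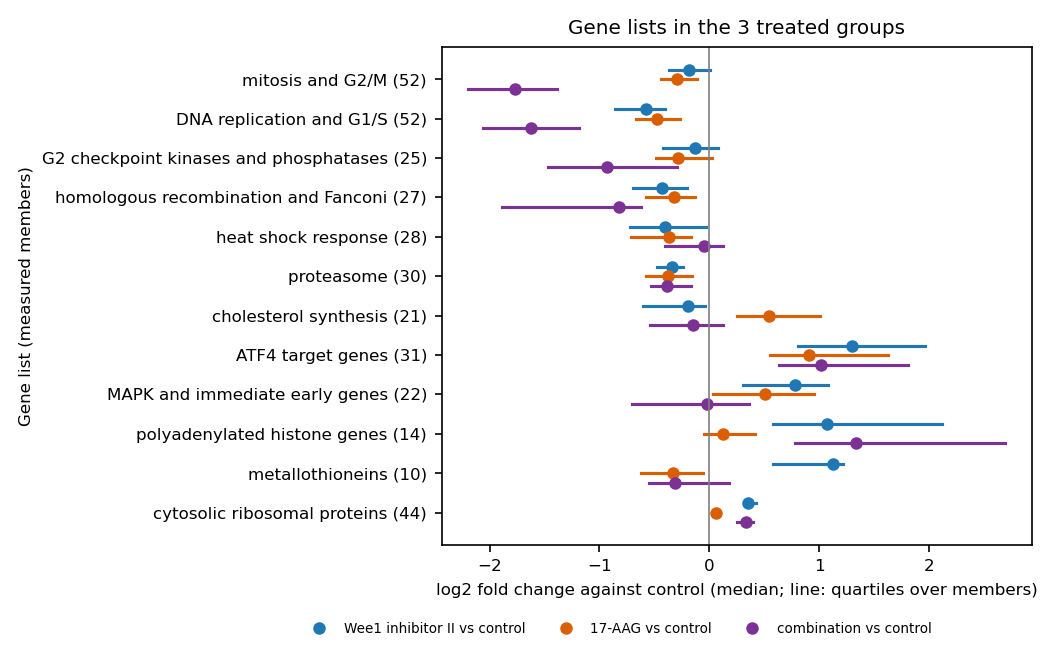
Median (point) and quartiles (line) of the log2 fold change against control over the measured members of 12 gene lists, as measured, with 1 colour per treated group. The mitosis list has a median of -0.19 with Wee1 inhibitor II, -0.29 with 17-AAG and -1.76 with both drugs.

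With both drugs 11 of 14 histone genes rose and none fell (11 and 1 adjusted over the list alone). The histone list stood at a median of 1.22 (camera adjusted p = 6.14e-05, and adjusted p = 0.0706 with an estimated correlation), with H2AC6 at 3.22 ± 0.12 (adjusted p = 5.73e-06). Of 31 ATF4 targets 23 rose and none fell (24 and 0 adjusted over the list alone). The ATF4 list stood at a median of 0.90 (camera adjusted p = 1.85e-10, and adjusted p = 0.336 with an estimated correlation), with ASNS at 2.30 ± 0.14 (adjusted p = 2.40e-05). Of 44 ribosomal protein genes 26 rose and none fell (35 and 0 adjusted over the list alone). The ribosomal protein list stood at a median of 0.22 (camera adjusted p = 6.96e-09, and adjusted p = 0.508 with an estimated correlation), with RPL3 at 0.49 ± 0.08 (adjusted p = 0.00296), a call lost with each array centred on its median (0.29). Of 30 proteasome genes 16 fell and 1 rose (19 and 1 adjusted over the list alone). The proteasome list stood at a median of -0.50 (camera adjusted p = 3.83e-08, and adjusted p = 0.336 with an estimated correlation), with PSMD11 at -0.85 ± 0.11 (adjusted p = 0.000627), a call lost with the mean of a gene's probe sets (-0.49). Of 33 hypoxia genes 13 fell and 2 rose (14 and 2 adjusted over the list alone). The hypoxia list stood at a median of -0.25 (camera adjusted p = 0.00124, and adjusted p = 0.117 with an estimated correlation), with ADM, which codes for adrenomedullin, at -1.09 ± 0.08 (adjusted p = 5.99e-05). Of 21 cholesterol genes 7 fell and 2 rose (10 and 2 adjusted over the list alone). The cholesterol list stood at a median of -0.27 (camera adjusted p = 0.0186, and adjusted p = 0.336 with an estimated correlation), with ACAT2 at -1.79 ± 0.14 (adjusted p = 6.32e-05).

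Of the 16 largest changes with both drugs 14 belonged to genes with a signal under 100 in both groups, such as SPEF2 (4.53 ± 0.48, adjusted p = 0.000273) and GSAP (-4.79 ± 0.66, adjusted p = 0.000972), both rough values. Among brighter genes LTBP2, a matrix protein gene, changed by 4.04 ± 0.61 (adjusted p = 0.00163), C1S by 3.42 ± 0.19 (adjusted p = 1.72e-05) and the embryonic globin gene HBE1 by 3.51 ± 0.16 (adjusted p = 1.17e-05). The control signals of LTBP2 (8.24) and C1S (16.2) lie below the array medians, so these fold changes are only rough. The long noncoding RNA LINC02915 changed by -4.10 ± 0.22 (adjusted p = 1.72e-05), which is rough too, as its signal with both drugs (22.5) lies within the array medians. The wider ACTB gap of the 17-AAG arrays was present here too (0.96 against 0.69 in control). With each array centred on its median 1933 genes rose and 2805 fell, against 3306 and 2233 as deposited, and with control replicate 2 included the count was 1856. Of the 17 pigment cell genes 14 rose and 1 fell (median 0.57 as measured, camera p = 2.28e-05 without adjustment, and p = 0.0423 with an estimated correlation).

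Against 17-AAG alone, adding Wee1 inhibitor II lowered the same class of genes. All 52 mitosis genes fell, and CDK1 fell from a signal of 4250 to 962 (log2 fold change -2.14 ± 0.16, adjusted p = 0.000119). E2F8 changed by -3.10 ± 0.10 (adjusted p = 5.87e-06), MKI67 by -2.72 ± 0.28 (adjusted p = 0.00044) and TYMS, which codes for thymidylate synthase, by -2.27 ± 0.10 (adjusted p = 1.27e-05). Of 21 cholesterol genes 15 fell and none rose, with INSIG1 from 1340 to 309 (-2.12 ± 0.16, adjusted p = 0.000117). DNAJB1 rose from 510 to 889 (0.80 ± 0.08, adjusted p = 0.000499). This comparison bears most directly on what Wee1 inhibition adds to Hsp90 inhibition. In limma 2148 genes rose and 1668 fell, 3816 in all, 3106 of them with a signal of at least 100 in either group; the ACTB gap was 0.96 in both groups.

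The mitosis list had a median of -1.69 relative to all genes (camera adjusted p = 8.56e-58, and adjusted p = 0.00188 with an estimated correlation; 52 fell adjusted over the list alone). Of 52 replication genes 47 fell and 1 rose (48 and 1 adjusted over the list alone). The replication list stood at a median of -1.22 (camera adjusted p = 1.65e-37, and adjusted p = 0.0113 with an estimated correlation), with RRM2 at -2.69 ± 0.10 (adjusted p = 7.25e-06). Of 25 G2 checkpoint genes 16 fell and 1 rose (18 and 2 adjusted over the list alone). The G2 checkpoint list stood at a median of -0.78 (camera adjusted p = 1.68e-10, and adjusted p = 0.00188 with an estimated correlation), with WEE1 at -1.09 ± 0.10 (adjusted p = 0.00023) and the phosphatase gene CDC25C at -2.16 ± 0.15 (adjusted p = 8.14e-05). Of 27 recombination genes 14 fell and none rose (17 and 0 adjusted over the list alone). The recombination list stood at a median of -0.73 (camera adjusted p = 1.13e-10, and adjusted p = 0.00188 with an estimated correlation), with BARD1 at -1.89 ± 0.10 (adjusted p = 3.05e-05). The cholesterol genes had a median of -0.98 (camera adjusted p = 3.55e-14, and adjusted p = 0.0113 with an estimated correlation; 15 fell and 0 rose adjusted over the list alone). Of 22 MAPK genes 11 fell and 1 rose (13 and 1 adjusted over the list alone). The MAPK list stood at a median of -0.67 (camera adjusted p = 1.64e-07, and adjusted p = 0.149 with an estimated correlation), with SPRY2, a feedback inhibitor of the pathway, at -1.30 ± 0.10 (adjusted p = 0.000105). Of 33 hypoxia genes 10 fell and 1 rose (11 and 1 adjusted over the list alone). The hypoxia list stood at a median of -0.24 (camera adjusted p = 0.000711, and adjusted p = 0.0877 with an estimated correlation), with PDK1 at -1.19 ± 0.11 (adjusted p = 0.000271).

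Of 30 p53 target genes 7 fell and 2 rose (9 and 3 adjusted over the list alone). The p53 list stood at a median of -0.31 (camera adjusted p = 0.0424, and adjusted p = 0.109 with an estimated correlation). Its call was lost without 17-AAG replicate 1, combination replicate 1 or combination replicate 3 (medians of -0.18, -0.15 and -0.21 as measured). It was also lost without the dimmest 40% of genes, with signals below 32 set to 32 and with the mean of a gene's probe sets. The repair gene DDB2 changed by -0.78 ± 0.09 (adjusted p = 0.000842), and the oxidoreductase gene TP53I3 went the other way at 1.05 ± 0.14 (adjusted p = 0.00142). Of 28 heat shock genes 10 rose and 1 fell (12 and 1 adjusted over the list alone). The heat shock list stood at a median of 0.16 (camera adjusted p = 5.79e-05, and adjusted p = 0.270 with an estimated correlation), with SERPINH1 at 2.45 ± 0.09 (adjusted p = 7.04e-06) and DNAJB4 at 1.16 ± 0.13 (adjusted p = 0.000809). Of 14 histone genes 9 rose and none fell (11 and 1 adjusted over the list alone). The histone list stood at a median of 1.32 (camera adjusted p = 4.47e-06, and adjusted p = 0.0332 with an estimated correlation), with H2AC6 at 2.99 ± 0.10 (adjusted p = 7.04e-06). Of 44 ribosomal protein genes 20 rose and none fell (33 and 0 adjusted over the list alone). The ribosomal protein list stood at a median of 0.15 (camera adjusted p = 2.50e-10, and adjusted p = 0.377 with an estimated correlation), with RPL14 at 0.39 ± 0.07 (adjusted p = 0.00523), a call lost with each array centred on its median (0.19) and with the mean of a gene's probe sets (0.34). Of the 16 largest changes 15 belonged to genes with a signal under 100 in both groups, such as NTN4 (4.28 ± 0.68, adjusted p = 0.00379) and TMPO-AS1 (-3.55 ± 0.61, adjusted p = 0.00528). Both values are rough, and that of NTN4 became 0 with signals below 32 set to 32. Among brighter genes CEMIP, which codes for a hyaluronan-binding protein, changed by 2.62 ± 0.22 (adjusted p = 0.000201). With each array centred on its median 790 genes rose and 2349 fell, against 2148 and 1668 as deposited, and with control replicate 2 included in the fit of all groups the count was 542, and 2370 with the mean of a gene's probe sets.

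**Figure D3:**
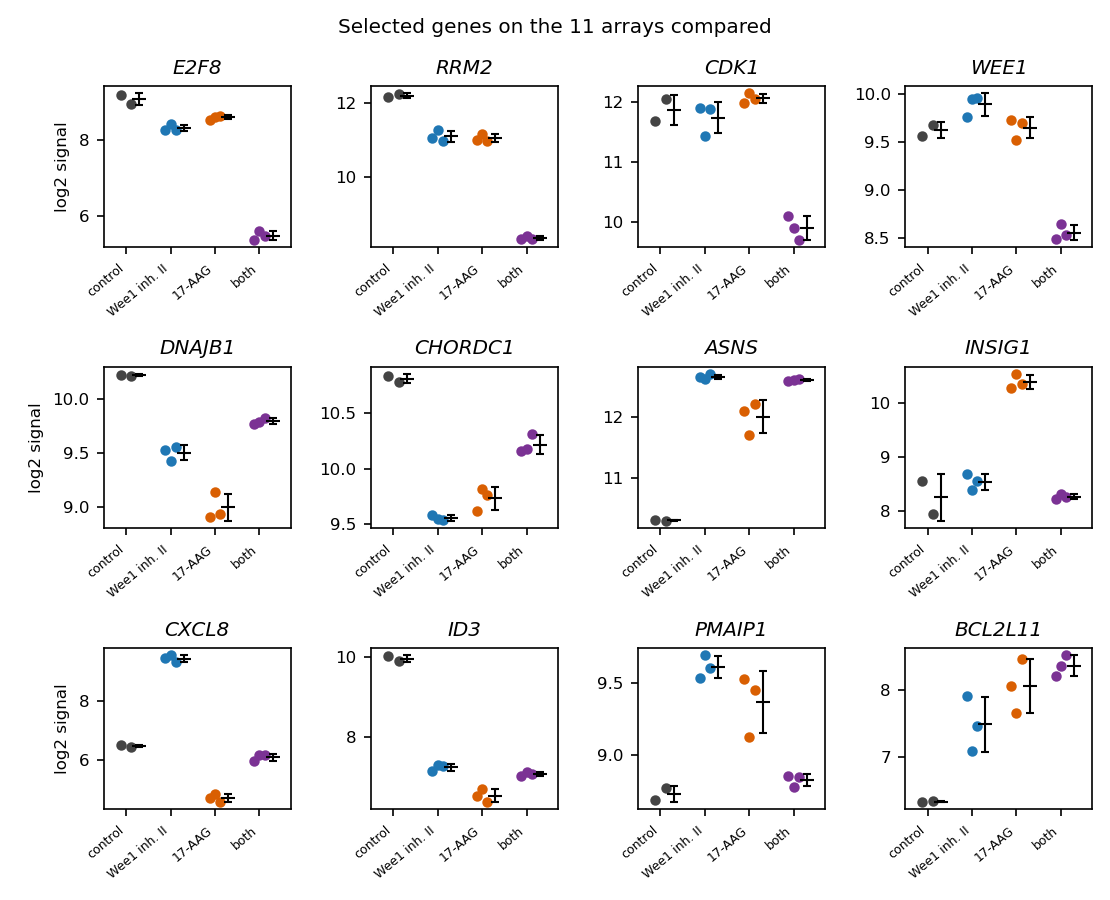
Log2 signal of 12 genes on the 11 arrays compared, 1 point per array, with the mean and SD of each group as a bar. E2F8 has a mean signal of 532 in control, 315 with Wee1 inhibitor II, 383 with 17-AAG and 44.5 with both drugs.

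Adding 17-AAG to Wee1 inhibitor II lowered the division genes too, with genes of the inflammatory, metallothionein and glucocorticoid receptor lists. All 52 mitosis genes fell, with TOP2A, the topoisomerase of mitotic chromosomes, from a signal of 3890 to 1050 (log2 fold change -1.88 ± 0.08, adjusted p = 9.94e-06). CXCL8, which codes for interleukin 8, fell from 701 to 68.5 (-3.36 ± 0.10, adjusted p = 5.84e-06), and 10 of 29 inflammatory and NF-kB target genes fell while 1 rose. MT2A fell from 3590 to 1240 (-1.53 ± 0.10, adjusted p = 4.71e-05) and CEBPD, a glucocorticoid-inducible factor, from 2070 to 630 (-1.72 ± 0.10, adjusted p = 3.82e-05). This comparison shows the effect of 17-AAG after Wee1 inhibitor II. In limma 1438 genes rose and 1353 fell, 2791 in all, 2398 of them with a signal of at least 100 in either group.

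The mitosis list had a median of -1.69 relative to all genes (camera adjusted p = 4.30e-61, and adjusted p = 0.00205 with an estimated correlation; 52 fell adjusted over the list alone). Of 52 replication genes 46 fell and none rose (49 and 0 adjusted over the list alone). The replication list stood at a median of -0.97 (camera adjusted p = 1.77e-37, and adjusted p = 0.0132 with an estimated correlation), with RRM2 at -2.73 ± 0.10 (adjusted p = 5.84e-06). Of 25 G2 checkpoint genes 14 fell and 1 rose (17 and 1 adjusted over the list alone). The G2 checkpoint list stood at a median of -0.68 (camera adjusted p = 4.10e-10, and adjusted p = 0.00205 with an estimated correlation), with WEE1 at -1.33 ± 0.10 (adjusted p = 8.11e-05). Of 27 recombination genes 13 fell and none rose (17 and 0 adjusted over the list alone). The recombination list stood at a median of -0.58 (camera adjusted p = 4.10e-10, and adjusted p = 0.00205 with an estimated correlation), with FANCI at -1.55 ± 0.08 (adjusted p = 2.41e-05). Of 12 CDK inhibitors, D cyclins and RB family genes 5 fell and none rose (7 and 0 adjusted over the list alone). The CDK inhibitor list stood at a median of -0.33 (camera adjusted p = 0.00016, and adjusted p = 0.0144 with an estimated correlation), with CCND1 at -0.51 ± 0.08 (adjusted p = 0.00292) and CDKN1C at -0.85 ± 0.16 (adjusted p = 0.00911), a call lost with the mean of a gene's probe sets (-0.58). Of 29 Hsp90 clients 9 fell and 3 rose (10 and 3 adjusted over the list alone). The Hsp90 client list stood at a median of -0.19 (camera adjusted p = 0.0139, and adjusted p = 0.0644 with an estimated correlation), with HIF1A at -0.99 ± 0.08 (adjusted p = 0.000112) and the receptor kinase gene MET, in the other direction, at 2.71 ± 0.22 (adjusted p = 0.000152). Of 28 heat shock genes 9 rose and none fell (12 and 0 adjusted over the list alone). The heat shock list stood at a median of 0.21 (camera adjusted p = 2.13e-06, and adjusted p = 0.171 with an estimated correlation), with HSPA4L at 2.25 ± 0.13 (adjusted p = 3.08e-05).

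The inflammatory list had a median of -0.46 (camera adjusted p = 0.00041, and adjusted p = 0.0144 with an estimated correlation; 11 fell and 1 rose adjusted over the list alone). Of 10 genes of the metallothionein list 6 fell and none rose (7 and 0 adjusted over the list alone). The metallothionein list stood at a median of -1.01 (camera adjusted p = 3.86e-05, and adjusted p = 0.0203 with an estimated correlation). Of 13 glucocorticoid receptor targets, which include MT2A, 6 fell and none rose (7 and 0 adjusted over the list alone). The glucocorticoid receptor list stood at a median of -0.75 (camera adjusted p = 1.66e-05, and adjusted p = 0.0132 with an estimated correlation). Of 13 aryl hydrocarbon receptor targets 4 fell and none rose (4 and 0 adjusted over the list alone). The aryl hydrocarbon receptor list stood at a median of -0.55 (camera adjusted p = 0.01, and adjusted p = 0.131 with an estimated correlation), with NQO1 at -0.75 ± 0.07 (adjusted p = 0.000231), while CYP1A1 stood at -0.58 ± 0.34 (adjusted p = 0.342). Of 22 MAPK genes 11 fell and none rose (13 and 0 adjusted over the list alone). The MAPK list stood at a median of -0.63 (camera adjusted p = 8.42e-10, and adjusted p = 0.0674 with an estimated correlation), with JUN at -2.37 ± 0.23 (adjusted p = 0.000327). Of 21 SRF or YAP targets 8 fell and 2 rose (8 and 2 adjusted over the list alone). The SRF or YAP list stood at a median of -0.43 (camera adjusted p = 0.000158, and adjusted p = 0.0144 with an estimated correlation), with CCN1 at -2.06 ± 0.12 (adjusted p = 2.79e-05). Of 24 autophagy and lysosome genes 7 rose and none fell (9 and 1 adjusted over the list alone). The autophagy list stood at a median of 0.20 (camera adjusted p = 0.0139, and adjusted p = 0.0715 with an estimated correlation), with the protease gene CTSL at 0.95 ± 0.09 (adjusted p = 0.000218), and its call was lost without the dimmest 40% of genes. Of the 8 largest changes 7 belonged to genes with a signal under 100 in both groups, and the exception was CEMIP at 4.19 ± 0.22 (adjusted p = 2.28e-05, signal 345 against 18.8, so only a rough fold change). The ACTB gap was 0.96 on the arrays with both drugs against 0.68 with Wee1 inhibitor II alone. With control replicate 2 included in the fit of all groups the count was 389, and 1664 with the mean of a gene's probe sets. Of the 17 pigment cell genes 9 rose and 1 fell (median 0.90 as measured, camera p = 7.77e-10 without adjustment, and p = 0.00874 with an estimated correlation).

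The effects of the drugs did not add up on the log2 scale for many genes. The interaction, the effect of Wee1 inhibitor II with 17-AAG minus its effect without, was below 0 for 49 of 52 mitosis genes and above 0 for none: TOP2A stood at -1.65 ± 0.12 (adjusted p = 0.000542) and CDK1 at -2.01 ± 0.24 (adjusted p = 0.00254). Heat shock genes went the other way, 14 of 28 above 0 and none below, with CHORDC1 at 1.74 ± 0.12 (adjusted p = 0.000542) and DNAJB1 at 1.52 ± 0.13 (adjusted p = 0.000831). For 20 of 31 ATF4 targets the effect of both drugs was below the sum of the single effects: ASNS had signals of 1270 in control, 6500 with Wee1 inhibitor II, 4140 with 17-AAG and 6270 with both (-1.76 ± 0.19, adjusted p = 0.00156). In limma 953 genes lay above 0 and 1378 below, 2331 in all, 2065 with a signal of at least 100 in some group.

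The mitosis list had a median interaction of -1.18 relative to all genes (camera adjusted p = 1.07e-41, and adjusted p = 0.00805 with an estimated correlation; 52 below 0 adjusted over the list alone). Of 52 replication genes 19 lay below 0 and 1 above (26 and 3 adjusted over the list alone). The replication list stood at a median of -0.42 (camera adjusted p = 1.13e-09, and adjusted p = 0.126 with an estimated correlation), with E2F8 at -2.35 ± 0.14 (adjusted p = 0.000378). Of 25 G2 checkpoint genes 10 lay below and none above (13 and 3 adjusted over the list alone). The G2 checkpoint list stood at a median of -0.40 (camera adjusted p = 0.00266, and adjusted p = 0.0851 with an estimated correlation), with WEE1 at -1.36 ± 0.14 (adjusted p = 0.00156). Of 27 recombination genes 8 lay below and 3 above (9 and 3 adjusted over the list alone). The recombination list stood at a median of -0.40 (camera adjusted p = 0.0224, and adjusted p = 0.0954 with an estimated correlation), with BARD1 at -1.51 ± 0.15 (adjusted p = 0.00141) and the damage sensor gene NBN at 0.99 ± 0.13 (adjusted p = 0.00313). The heat shock list had a median of 0.77 (camera adjusted p = 2.52e-14, and adjusted p = 0.0863 with an estimated correlation; 18 above and 0 below adjusted over the list alone). Of 30 proteasome genes 7 lay above and 1 below (12 and 1 adjusted over the list alone). The proteasome list stood at a median of 0.35 (camera adjusted p = 3.05e-07, and adjusted p = 0.274 with an estimated correlation), with PSMD12 at 0.91 ± 0.14 (adjusted p = 0.00627). Of 31 ATF4 targets 20 lay below and 2 above (23 and 2 adjusted over the list alone). The ATF4 list stood at a median of -1.05 (camera adjusted p = 4.80e-12, and adjusted p = 0.197 with an estimated correlation), with ATF3 at -2.44 ± 0.26 (adjusted p = 0.00165).

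Of 22 MAPK genes 16 lay below 0 and none above (17 and 0 adjusted over the list alone). The MAPK list stood at a median of -1.19 (camera adjusted p = 1.82e-13, and adjusted p = 0.0851 with an estimated correlation), with JUN at -3.07 ± 0.34 (adjusted p = 0.00191) and EGR1 at -4.14 ± 0.50 (adjusted p = 0.00248). Of 21 cholesterol genes 5 lay below and none above (8 and 0 adjusted over the list alone). The cholesterol list stood at a median of -0.47 (camera adjusted p = 4.42e-05, and adjusted p = 0.0954 with an estimated correlation), with INSIG1 at -2.41 ± 0.24 (adjusted p = 0.00135). Of 13 glucocorticoid receptor targets 5 lay below and none above (8 and 0 adjusted over the list alone). The glucocorticoid receptor list stood at a median of -0.62 (camera adjusted p = 0.000231, and adjusted p = 0.0704 with an estimated correlation), with CEBPD at -2.79 ± 0.16 (adjusted p = 0.000281). The interaction was called for 4 more lists. Of 29 Hsp90 clients 9 lay below and 2 above (10 and 2 adjusted over the list alone). The Hsp90 client list stood at a median of -0.22 (camera adjusted p = 0.0303, and adjusted p = 0.0954 with an estimated correlation). Of 12 genes of the CDK inhibitor list 4 lay below and 1 above (6 and 1 adjusted over the list alone). The CDK inhibitor list stood at a median of -0.48 (camera adjusted p = 0.0224, and adjusted p = 0.0954 with an estimated correlation). Of 10 genes of the metallothionein list 2 lay below and none above (5 and 1 adjusted over the list alone). The metallothionein list stood at a median of -0.86 (camera adjusted p = 0.0317, and adjusted p = 0.160 with an estimated correlation). Of 21 SRF or YAP targets 4 lay below and 1 above (4 and 1 adjusted over the list alone). The SRF or YAP list stood at a median of -0.24 (camera adjusted p = 0.0296, and adjusted p = 0.0954 with an estimated correlation).

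Without control replicate 3 the calls of these 4 lists were lost, at medians of -0.31, -0.41, -0.74 and -0.17 as measured. The call of the Hsp90 clients was also lost without Wee1 inhibitor II replicate 2 (-0.27), that of the metallothionein list without 17-AAG replicate 2 (-0.86) or combination replicate 1 (-0.48) and that of the SRF or YAP targets without 17-AAG replicate 2 (-0.16). A replicate block ended the calls of the Hsp90 clients, the metallothionein list and the SRF or YAP targets. Every probe set tested, or the mean of a gene's probe sets, ended those of the Hsp90 clients, the metallothionein list and the recombination list, and the last was also lost without the dimmest 40% of genes. Among genes with a signal of at least 100 in some group SERPINA3 stood at -3.78 ± 0.28 (adjusted p = 0.000542), ZEB1 at -4.16 ± 0.38 (adjusted p = 0.00112), CEMIP at 3.86 ± 0.33 (adjusted p = 0.000899) and ID3 at 3.25 ± 0.15 (adjusted p = 0.000176), and each of the 8 largest values belonged to a gene with a signal under 100 in all groups, such as C8G (5.53 ± 0.96, adjusted p = 0.00988, signals 1.72 to 27.5). With signals below 32 set to 32 C8G stood at 0.028 and its call was lost. ZEB1 in control (17.9) and CEMIP with Wee1 inhibitor II (18.8) had signals within the array medians, so both values are rough. The count of 2331 was 1361 without control replicate 1, 1350 without control replicate 3, 1522 without 17-AAG replicate 1, 119 with control replicate 2 included, 1255 with each array centred on its median, 1483 with a replicate block and 1099 with the mean of a gene's probe sets. It was 3558 without the dimmest 40% of genes and 3716 among genes with a signal of at least 100. The mean of a gene's probe sets also ended the calls of CHORDC1 (1.57), ASNS (-1.95) and NBN (0.86).

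Single genes of the intrinsic apoptotic pathway were called, while its lists did not pass in any of the 6 comparisons. Of 22 measured pro-apoptotic genes of the mitochondrial pathway 4 rose and 7 fell with Wee1 inhibitor II (6 and 8 adjusted over the list alone; camera adjusted p = 0.268), 3 rose and 2 fell with 17-AAG (3 and 2; adjusted p = 0.978), and 3 rose and 4 fell with both drugs (4 and 5; adjusted p = 0.273). Of 14 anti-apoptotic genes 2 rose and 5 fell (2 and 5 adjusted over the list alone; adjusted p = 0.198), 3 rose and 3 fell (3 and 3; adjusted p = 0.930), and 3 rose and 5 fell (4 and 6; adjusted p = 0.275) in the same order. For both drugs against 17-AAG, none of the pro-apoptotic genes rose and 4 fell (1 and 5 adjusted over the list alone; camera adjusted p = 0.0728), and 2 of the anti-apoptotic genes rose and 4 fell (2 and 5; adjusted p = 0.0654). BCL2L11, the gene of the BH3-only protein BIM, changed by 1.15 ± 0.28 with Wee1 inhibitor II (adjusted p = 0.0176), 1.73 ± 0.28 with 17-AAG (adjusted p = 0.00521) and 2.03 ± 0.28 with both (adjusted p = 0.000986), and its value of 0.30 ± 0.25 for both drugs against 17-AAG (adjusted p = 0.476) did not pass. PMAIP1, the gene of NOXA, changed by 0.88 ± 0.13 (adjusted p = 0.00165) and 0.64 ± 0.13 (adjusted p = 0.0112) with the single drugs and stood at 0.10 ± 0.13 with both (adjusted p = 0.662), an interaction of -1.42 ± 0.17 (adjusted p = 0.00236). BIRC5, the gene of survivin and a mitosis gene, changed by -0.36 ± 0.10 (adjusted p = 0.0256), -0.42 ± 0.10 (adjusted p = 0.0205) and -2.22 ± 0.10 (adjusted p = 9.46e-06).

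MCL1, an anti-apoptotic gene, changed by 0.81 ± 0.11 with Wee1 inhibitor II (adjusted p = 0.0012) and by 0.38 ± 0.11 with both drugs (adjusted p = 0.0288), where 3 of its 6 probe sets had the same sign, and stood at 0.06 ± 0.11 with 17-AAG (adjusted p = 0.790). CDKN1A, the p53-inducible gene of p21, changed by 1.20 ± 0.36 with Wee1 inhibitor II (adjusted p = 0.0425) and stood at 0.42 ± 0.36 with 17-AAG (adjusted p = 0.519) and 0.02 ± 0.36 with both drugs (adjusted p = 0.981). The p53 targets did not pass as a list against control, with 8 of 30 rising and 4 falling with Wee1 inhibitor II (9 and 4 adjusted over the list alone; camera adjusted p = 0.592), 5 and 4 with 17-AAG (5 and 5; adjusted p = 0.978) and 7 and 7 with both (9 and 7; adjusted p = 0.434). Without control replicate 1 or without control replicate 3, the calls of BCL2L11 (1.15 and 1.16), BIRC5 (-0.41 and -0.31) and CDKN1A (0.97 and 1.43) with Wee1 inhibitor II were lost, and so were those of PMAIP1 (0.60 and 0.68) and BIRC5 (-0.46 and -0.37) with 17-AAG and of MCL1 with both drugs (0.45 and 0.32). With the mean of a gene's probe sets, the calls of BCL2L11 (0.27), MCL1 (0.35), BIRC5 (-0.30) and CDKN1A (1.20) with Wee1 inhibitor II were lost. The call of BIRC5 was also lost without replicate 1 or 3 of Wee1 inhibitor II (-0.35 and -0.34) or of 17-AAG (-0.39 and -0.39) in the comparison with that drug, and that of MCL1 without replicate 1, 2 or 3 of the combination (0.41, 0.38 and 0.36). The call of CDKN1A was lost without replicate 1 or 2 of Wee1 inhibitor II (0.92 and 1.30), and its value of 1.20 did not pass without 17-AAG replicate 1, combination replicate 1 or combination replicate 2. It was also lost with array weights, a replicate block, quantile normalisation, centring, every probe set tested and the floor of 32. Centring ended the calls of BIRC5 with 17-AAG and MCL1 with both drugs, a block that of MCL1, quantile normalisation that of BIRC5 with Wee1 inhibitor II, and every probe set tested those of BIRC5 with either drug.

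Several other lists gave no call in any comparison. With Wee1 inhibitor II, 17-AAG and both drugs in turn, the camera adjusted p was 0.457, 0.794 and 0.687 for 17 death receptor genes (1 rose and 0 fell, 2 and 1, 3 and 1), 0.755, 0.785 and 0.562 for 24 chaperones and other genes of the unfolded protein response of the endoplasmic reticulum (6 and 5, 5 and 3, 6 and 6) and 0.378, 0.0938 and 0.279 for 27 NRF2 targets and oxidative stress genes (6 and 8, 4 and 8, 7 and 10). It was 0.210, 0.930 and 0.275 for 39 interferon response genes (10 and 4, 7 and 5, 13 and 4) and 0.198, 0.978 and 0.275 for 24 epithelial and mesenchymal genes (7 and 3, 3 and 2, 6 and 1). Among the lists of other cell types, it was 0.592, 0.978 and 0.402 for 13 fibroblast markers (0 and 1, 1 and 1, 0 and 2), 0.995, 0.978 and 0.902 for 11 blood cell markers (none called) and 0.450, 0.970 and 0.495 for 9 markers of androgen-responsive prostate lines (0 and 1, 1 and 0, 0 and 0). Counts adjusted over the list alone were 1 and 0, 2 and 1, 3 and 1 for the death receptor genes, 7 and 5, 5 and 6, 8 and 8 for the unfolded protein response, 8 and 8, 4 and 8, 7 and 10 for NRF2, 12 and 4, 7 and 6, 15 and 4 for interferon and 9 and 3, 3 and 2, 6 and 1 for the epithelial and mesenchymal genes. For the fibroblast markers they were 0 and 1, 1 and 1 and 0 and 1, for the blood cell markers 0 throughout, and for the markers of androgen-responsive lines 0 and 1, 1 and 1 and 0 and 0.

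The effect of each drug was similar only in part with and without the other. Across 19775 genes, which are not independent replicates, the log2 fold changes of Wee1 inhibitor II with and without 17-AAG correlated at r = 0.223 (Spearman's rho 0.258), and those of 17-AAG with and without Wee1 inhibitor II at r = 0.098 (rho 0.115); neither pair shares an array. Over the 8278 genes with a mean signal of at least 100 the values were 0.472 and 0.303.

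Against the shared controls, Wee1 inhibitor II and 17-AAG had 1248 genes higher and 794 lower in common, with 186 called in opposite directions, where independent lists would share 286 and 139. Wee1 inhibitor II and the combination shared 2104 and 1331 (133 opposite; 481 and 231 if independent), and 17-AAG and the combination 1479 and 925 (66 opposite; 328 and 152 if independent). The fold changes correlated across genes at r = 0.576, 0.673 and 0.627 in that order. In 100 simulations of unchanged groups, controls simulated too, r was 0.599 in each case. The covariance was 0.372, 0.509 and 0.425 against a simulated 0.248, 0.248 and 0.249, and a simulation shared 0.03, 0.01 and 0 calls on average. Unchanged data yield few calls, so these counts are no yardstick. The 2 real control arrays were not in the simulations and could not be split into parts of at least 2. Part of the excess may come from them. In all 2042, 3435 and 2404 genes were shared in the same direction, and 1042, 2266 and 1297 without control replicate 3.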

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

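The counts for other splits were planned before the data were examined, while the tests of the 3 patterns here were chosen after their results were seen. Among the 10 splits of the 6 arrays with 17-AAG alone and with both drugs into 3 and 3, only the real split, 1 of 10, reached its count of 3816 genes, and the highest other count was 1. For the arrays with Wee1 inhibitor II alone and with both drugs it was again 1 of 10, with 2791 genes against a highest other count of 2. With 10 splits no share under 0.05 can arise, since the smallest is 0.1.

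On control replicate 2 weak signal alone was excluded because 391 genes were at least 4-fold above every other array, beside 276 at least 4-fold below. A mixture with the cells of the other arrays was excluded because the median pigment cell marker kept 0.324% of its level. The pigment cell markers stood at a median of -8.23 (log2) against the mean of the 11. They were picked from these values, so they are no test of cells of another line. CTNNA1 (2560 to 5040) and STAT3 (819 to 1300) exclude a line that lacks both genes, as PC3 is known to, on the 11 arrays. On all 11 arrays 16 of 17 pigment cell markers lay above, and all 3 prostate markers below, control replicate 2. Which lines these were stays open. All drug effects here are those of cells with pigment cell transcripts and may not hold for PC3.

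The mitosis genes lay lower with both drugs than the single effects add up to. Array scaling was excluded, as the weakest median over 3 scalings was -1.19, and so was a single control array, as the weakest median without either was -1.21. RNA degradation was excluded, as the median was -1.58 between both drugs and 17-AAG, where the ACTB gap differed by 0.00. A smaller share of dividing cells or repression in each cell could explain the pattern, and the arrays cannot tell these apart.

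The heat shock list lay lower on the 17-AAG arrays, although blocking Hsp90 is known to raise its genes. The list was as low with Wee1 inhibitor II alone (-0.40 against -0.37 as measured) and at -0.05 with both drugs. High controls, not tested, could give both falls. Array scaling was excluded, as the weakest median over 3 scalings was -0.36. With control and 17-AAG labels exchanged, the 17-AAG effects with and without Wee1 inhibitor II correlated at -0.303 across bright genes. This only turns the sign of 0.303 as labelled (-0.309 to -0.285 without 1 array), so it is no test. Against an exchange, the correlation of the Wee1 inhibitor II effects fell from 0.472 to 0.194. The ACTB gap grouped 17-AAG with both drugs (0.96 and 0.96) and control with Wee1 inhibitor II (0.69 and 0.68), as the labels do. The exchange stays open, because the list was higher with both drugs than with Wee1 inhibitor II (0.21), as an exchange would need. A feedback at 48 h that outlasts an early rise may also lower these genes, and no earlier time point was analysed here.

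The interaction was called for 2331 genes. As measured, its median was 0.74 for the heat shock list, -0.25 for the Hsp90 clients, -1.21 for mitosis, -0.45 for replication, -0.43 for the G2 checkpoint and -0.42 for recombination. It was -0.50 for CDK inhibitors, -1.08 for ATF4 targets, -0.50 for cholesterol synthesis, -0.88 for the metallothionein list and -0.65 for glucocorticoid receptor targets. It was 0.33 for the proteasome, -1.22 for MAPK genes and -0.26 for SRF or YAP targets. Of these 14 lists only mitosis kept its call with an estimated correlation (adjusted p = 0.00805, against 0.0704 to 0.274 for the others), and the Hsp90 clients, CDK inhibitors, metallothionein list and SRF or YAP targets lost theirs without control replicate 3. The interaction stood at 3.86 for CEMIP, 3.25 for ID3, -4.16 for ZEB1, -4.14 for EGR1, -3.78 for SERPINA3 and 5.53 for C8G, where CEMIP, ZEB1 and C8G are rough and the call of C8G was lost with signals below 32 set to 32 (0.028). Among stress and division genes it stood at 1.74 for CHORDC1, 1.52 for DNAJB1, -1.65 for TOP2A, -2.35 for E2F8, -1.36 for WEE1, -2.01 for CDK1, -1.51 for BARD1 and 0.99 for NBN. It stood at -1.76 for ASNS, -2.44 for ATF3, -3.07 for JUN, -2.41 for INSIG1, -2.79 for CEBPD, -1.42 for PMAIP1 and 0.91 for PSMD12.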

How the results depend on the processing

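Including control replicate 2 with equal weight lowered all 6 counts. They fell to 1268 genes for Wee1 inhibitor II against control, 480 for 17-AAG, 1856 for both drugs, 542 for both drugs against 17-AAG, 389 against Wee1 inhibitor II and 119 for the interaction. The effects of Wee1 inhibitor II with and without 17-AAG then correlated at 0.128 and those of 17-AAG at 0.112, and the overlaps of calls were 267 between the single drugs, 821 between Wee1 inhibitor II and both drugs, and 344 between 17-AAG and both drugs. List medians in this part are as measured, without the median of all genes taken off. With Wee1 inhibitor II the sign changed for HSP90AA1 (0.029), HSP90AB1 (0.168), the mitosis list (0.150) and the G2 checkpoint list (0.016). With 17-AAG it changed for MMP8 (0.385), CCNB1 (0.023), MCL1 (-0.380), CDKN1A (-0.210), the mitosis list (0.078) and the G2 checkpoint list (0.062). With both drugs it changed for PMAIP1 (-0.407), MCL1 (-0.055), CDKN1A (-0.609) and ADM (0.131). Of the 145 called gene values in the report 77 kept their call in that fit, 64 lost it without a change of sign and 4 with one. Of 72 list calls 51 stayed and the others were lost. With array weights, where that array weighed 0.041, all 145 gene calls and 71 of 72 list calls stayed, all but that of the SRF or YAP targets in the interaction (-0.234), and the first correlation was 0.208.

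Without the dimmest 40% of genes the interaction had 3558 calls and the correlations were 0.468 and 0.259, and among bright genes alone it had 3716. With signals below 32 set to 32 the log2 fold changes of MGP with Wee1 inhibitor II and of NTN4 for both drugs against 17-AAG became 0. The calls of P2RY6 (0) and TGFBI (-0.335) with 17-AAG, of CDKN1A with Wee1 inhibitor II (1.196), of C8G in the interaction (0.028) and of the p53 list for both drugs against 17-AAG (-0.155) were lost. Without the dimmest 40% of genes 4 list calls were lost: the p53 list there (-0.214), the G2 checkpoint with Wee1 inhibitor II (-0.129), autophagy for both drugs against Wee1 inhibitor II (0.203) and recombination in the interaction (-0.396). At least a 2-fold change was met by 1468, 710, 1982, 882, 734 and 895 of the called genes, in the order of the counts in the first paragraph. An adjusted p under 0.01 was met by 2816, 1493, 3592, 1932, 1487 and 828.

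The mean of a gene's probe sets gave 3215 genes for Wee1 inhibitor II, 1768 for 17-AAG and 1099 for the interaction. Both drugs had 2370 against 17-AAG and 1664 against Wee1 inhibitor II. The mean ended 15 gene calls without a change of sign. It ended 5 list calls: the metallothionein list with Wee1 inhibitor II (0.732), the p53 list for both drugs against 17-AAG (-0.155) and, in the interaction, the Hsp90 clients (-0.049), recombination (-0.370) and the metallothionein list (-0.486). MCL1 changed sign with 17-AAG (-0.483) and both drugs (-0.128, its call lost), and BCL2L11 for both drugs against 17-AAG (-0.102). With every probe set tested 8948 probe sets were called for both drugs, and the median values were -0.584 and -0.040 for MCL1 and -0.324 for BCL2L11 in those comparisons. The calls of CDKN1A (1.196) and BIRC5 (-0.321) with Wee1 inhibitor II, BIRC5 with 17-AAG (-0.502) and MCL1 with both drugs were then lost. So were 5 list calls: the metallothionein list with Wee1 inhibitor II (0.612), the G2 checkpoint with 17-AAG (-0.212) and, in the interaction, the Hsp90 clients (-0.109), recombination (-0.107) and the metallothionein list (-0.341).

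Centring each array on its median gave 2204 genes for 17-AAG and 1255 for the interaction, with PMAIP1 at -0.1 and CDKN1A at -0.175 with both drugs. It ended 5 gene calls: CDKN1A with Wee1 inhibitor II (0.968), BIRC5 with 17-AAG (-0.405), MCL1 (0.189) and RPL3 (0.292) with both drugs, and RPL14 for both drugs against 17-AAG (0.188). After quantile normalisation CDKN1A stood at -0.200 and the correlation of the Wee1 inhibitor II effects was 0.205, and the calls of CDKN1A (1.043) and BIRC5 (-0.282) with Wee1 inhibitor II were lost. No list changed its call under either scaling. With array weights on the 11 arrays CDKN1A stood at -0.011, and its call with Wee1 inhibitor II was lost (1.146). A fit of only the arrays compared called 2461 genes for Wee1 inhibitor II and 0 for 17-AAG in limma. With a correlation estimated for each list 50 of 72 list calls were lost and 22 stayed. The list test fry, which tests for any change and not against other genes, passed for all 72.

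The replicate numbers do not pair the samples: deviations from group means correlated at -0.137 to 0.096 (median -0.013) over 15 pairs of arrays with the same number and at -0.184 to 0.184 over 30 with different numbers. With the number as a block the interaction had 1483 genes and CDKN1A stood at -0.055 with both drugs. The block ended the calls of CDKN1A with Wee1 inhibitor II (1.120), of MCL1 with both drugs (0.398) and of 4 lists: the metallothionein list with Wee1 inhibitor II (1.075) and, in the interaction, the Hsp90 clients (-0.279), the metallothionein list (-0.823) and the SRF or YAP targets (-0.123).

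Leaving out each of the 11 arrays in turn gave 3225 to 4891 genes for Wee1 inhibitor II, 1705 to 3159 for 17-AAG, 4009 to 5494 for both drugs, 2739 to 3590 for both drugs against 17-AAG, 1996 to 2819 against Wee1 inhibitor II and 1350 to 2223 for the interaction. The correlations were 0.191 to 0.215 for Wee1 inhibitor II and 0.078 to 0.103 for 17-AAG. The overlaps were 1042 to 1983 between the single drugs, 2266 to 3437 between Wee1 inhibitor II and both drugs, and 1297 to 2311 between 17-AAG and both drugs. CDKN1A ranged from -0.209 to 0.249 with both drugs and MCL1 from -0.003 to 0.146 with 17-AAG. The cause of these shifts was not tested.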

Other observations

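The pigment cell list of 17 genes, drawn up after its values were seen, changed in some comparisons. With both drugs against 17-AAG 4 rose and 2 fell at a median of 0.08 as measured, which did not pass in camera (p = 0.503, and p = 0.707 with an estimated correlation). In the interaction 8 lay above 0 and 3 below at a median of 0.41 (p = 0.0014, and p = 0.104 with an estimated correlation).

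On control replicate 2, some of the fixed lists lay far from the 11 other arrays. The median log2 difference from their mean was 2.07 for the polyadenylated histone genes, 1.64 for the markers of androgen-responsive prostate lines, 1.26 for interferon response genes and -1.43 for ATF4 targets.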
